A study of Mus musculus with 12 samples.

How the data were processed

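The measurements were made on 12 one-colour (Cy5) microRNA arrays of mouse cells, 2 arrays in each of 6 groups. Per the labels' protocols, total RNA was isolated with a mirVana kit, extended with a poly(A) tail and joined to an oligonucleotide tag for dye staining. The groups were mouse embryonic fibroblasts (MEFs), embryonic stem cells (ESCs; array 1 from line CJ7, array 2 from line CGR8) and 4 kinds of induced pluripotent stem cells (iPSCs), and they were taken from the sample labels. Per the file headers, the deposited scanner values were median pixel densities of each spot, which are an intensity on a linear scale. They were not normalized and still contained background, and the files used here had no background column. The authors' deposited value table holds a processed intensity for 1189 probes. It is linear and has like medians on all arrays (25.2 to 32.0), but the method and the normalization that produced it are not given in the sources used here. The array maker and the scanner are not given there either.

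Each array held 3423 microRNA spots, 3 for each of 1141 mature mouse microRNAs, with 545 control spots and 257 empty spots. Of the probes, 13 carried the names of several microRNAs. Spot intensities were corrected by normexp with an offset of 50, fitted on all spots, taken to log2 and quantile normalized over the microRNA spots, and the 3 spots were averaged. The offset compresses the differences of dim microRNAs. A microRNA counted as detected on an array when it lay above the mean of the empty spots plus 3 SD. The 763 microRNAs detected on every array of at least 1 group were tested, and 416 of them were detected on all 12 arrays. Where a microRNA was not detected on any array of the dimmer group, its difference is a bound. It is then given as at least N-fold, the mean of the brighter group over the mean, per array, of the higher of the lowest detected signal and the microRNA's own.

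Signal over background limits the arrays as follows. The median of the empty spots was 163 on MEFs array 2, 73.1 on ESCs array 2 and 30.4 to 41.8 on the others, and 498 to 849 microRNAs were detected per array. Arrays of 1 group correlated at 0.963 to 0.981, and arrays of different pluripotent groups at 0.915 to 0.987, the highest being O-lenti array A with M3O-lenti LIF(+) array A. The number of arrays limits the precision of every comparison.

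Group means were fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays, so that the 6 groups shared 1 estimate of the spread (6 residual and 3.81 prior degrees of freedom). Contrasts were tested two-sided with limma's moderated statistic, and p-values were adjusted by the Benjamini-Hochberg method over the 763 microRNAs, with a threshold of 0.05. Errors beside log2 differences are standard errors from this fit. The ESCs arrays came from different lines. For the other groups the labels do not say that the 2 arrays came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The 6 comparisons set pluripotent cells against MEFs, LIF(+) iPSCs against ESCs, O-lenti against O-retro iPSCs, M3O-lenti against O-lenti iPSCs, LIF(-) against LIF(+) M3O-lenti iPSCs, and LIF(-) M3O-lenti iPSCs against the mean of the other pluripotent groups.

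The 15 lists of microRNAs were tested with limma's camera at a preset correlation of 0.01, adjusted over the 90 tests of lists and comparisons. They were the miR-290, miR-302, miR-17-92 with its paralogs, miR-183, miR-322, Dlk1-Dio3 and Sfmbt2 clusters, the let-7, miR-34 and miR-200 families (the last with miR-205), and markers of fibroblasts, muscle, neural cells, endoderm and liver, and blood cells. Camera with an estimated correlation and fry were run beside it, and no list passed with the estimated correlation. Groups, lists, comparisons, tests and alternative settings were chosen before the data were examined. So was the rule for the microRNAs named in each comparison. It takes the 10 largest increases and the 10 largest decreases among those that pass and whose arrays do not overlap between the sides. Where fewer than 5 pass in a direction, it takes the smallest p-values up to 5. Of each list, it takes the 2 members with the smallest p and the 2 with the highest level, and members of the miR-290 and miR-302 clusters may be named in every comparison.

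The alternatives covered background correction, normalization, detection filter, variance model, samples in the fit, the authors' value table, a replicate block and the leaving out of each array. The background taken from the empty spots, the correction for GC content and the leaving out of both bright-background arrays were added after seeing the data. The fit was tested on simulated data of 827 microRNAs. For the LIF(-) against LIF(+) contrast it called 55 of 100 changes of log2 size 1 and 87 of 100 of size 2, with 7 calls among 627 unchanged microRNAs. It estimated those sizes at medians of 0.591 and 1.16. For LIF(-) cells against the other pluripotent groups it called 68 and 95 of 100, with 12 calls among the 627 unchanged. The simulated spread was taken from residuals after normalization and drawn independently for each microRNA and array. Processing then compressed that spread again, so the rates on the real arrays may be lower. No genome was used, so no coordinates are given.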

Results

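MicroRNA levels were measured in MEFs, in 2 ESC lines and in 4 kinds of iPSCs, with 2 arrays per group, to look for microRNAs possibly linked to growth without leukemia inhibitory factor (LIF), the cytokine that keeps mouse pluripotent cells undifferentiated. O-retro iPSCs were made from MEFs with Oct4, Sox2, Klf4 and c-Myc in retroviral vectors. O-lenti iPSCs carried Oct4 in a lentiviral vector, which kept the transgene expressed. M3O-lenti iPSCs carried M3O, a fusion of Oct4 with a transactivation domain of MyoD, in its place. M3O-lenti LIF(-) iPSCs were made and kept without LIF, and the other iPSCs with it. The labels place the ESCs and the LIF(+) iPSCs on irradiated MEF feeder cells and do not state whether the LIF(-) cells had feeders. In a principal component analysis the first component held 60.8% of the variance and separated the MEFs from the pluripotent cells, and the next components held 12.1% and 8.57%.

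The pluripotent cells were set against MEFs, the starting cells of the iPSCs. All 14 measured members of the miR-290 cluster, the main microRNA cluster of mouse ESCs, were higher in pluripotent cells. miR-293-3p was at least 173-fold higher, miR-295-3p at least 148-fold, and miR-292-5p higher by 6.96 ± 0.23 (log2, SE). MicroRNA markers of fibroblasts were lower, with miR-29c-3p at -3.56 ± 0.22 and miR-145-5p, which is abundant in smooth muscle and mesenchymal cells, at -3.13 ± 0.23. All 9 let-7 microRNAs, whose processing is blocked by Lin28 in pluripotent cells, were lower, and let-7i-5p differed by -3.35 ± 0.28.

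By list, the 14 members of the miR-290 cluster had a median of 5.56, or 5.37 with undetected members at their bounds (limma camera adjusted p = 5.28e-20). The adjusted p was 0.184 with an estimated correlation, and all 14 also passed when adjusted over the list alone. Of 34 fibroblast markers, 31 were lower (32 adjusted over the list alone), with an adjusted p of 1.2e-17 and, with an estimated correlation, an adjusted p of 0.184. Their examples include miR-29a-3p at -3.09 ± 0.17, miR-199b-5p at -3.29 ± 0.28 and miR-125b-5p at -1.92 ± 0.22. miR-21-5p differed by -0.65 ± 0.20 (adjusted p = 0.0324) but by 0.24 (adjusted p = 0.741) when arrays were scaled to their 75th percentile. Without MEFs array 2 it differed by -0.32 (adjusted p = 0.423) and without MEFs array 1 by -0.99. Its adjusted p was 0.0522 without O-lenti array A and 0.0523 without ESCs array 2. The let-7 family was lower in 9 of 9 members, also adjusted over the list alone (adjusted p = 3.08e-06, and adjusted p = 0.549 with an estimated correlation).

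Of 22 members of the miR-17-92 and paralog clusters, which promote cell cycling, 10 were higher, or 11 adjusted over the list alone. Their adjusted p was 1.89e-04, and 0.549 with an estimated correlation. miR-363-3p was at least 7.98-fold higher, and miR-92a-3p was higher by 0.99 ± 0.15. Epithelial microRNAs were higher in 5 of 8 members of the miR-200 and miR-205 list, also adjusted over the list alone (adjusted p = 0.00408, and adjusted p = 0.603 with an estimated correlation). miR-200b-3p was at least 6.89-fold higher, miR-429-3p at least 4.98-fold, and miR-205-5p higher by 2.92 ± 0.19. In the miR-183 cluster 5 of 6 members were higher, and 6 adjusted over the list alone (adjusted p = 7.25e-04, and adjusted p = 0.549 with an estimated correlation), with miR-183-5p at 3.37 ± 0.28 and miR-182-5p at 2.42 ± 0.20.

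Of the 75 tested microRNAs of the imprinted Dlk1-Dio3 region (94 were on the array), 24 were lower and 3 higher (26 and 3 adjusted over the list alone). The list's adjusted p was 0.0026, and 0.801 with an estimated correlation, and miR-299-5p differed by -1.99 ± 0.19. Of 5 members of the miR-322 cluster 3 were lower, and 4 adjusted over the list alone (adjusted p = 0.0469, and adjusted p = 0.603 with an estimated correlation). That call was lost, with adjusted p from 0.0539 to 0.0975, on leaving out any 1 of both MEFs arrays, both ESCs arrays, O-lenti array A, M3O-lenti LIF(+) array A and M3O-lenti LIF(-) array B. In the miR-302 cluster, which is high in epiblast-like cells, 3 of 10 members on the array were detected often enough to be tested. Of these 3, 1 was higher, also adjusted over the list alone (list adjusted p = 0.279). It was miR-302d-3p, at least 2.66-fold (adjusted p = 0.0316). Its adjusted p rose to 0.158 without MEFs array 1, 0.167 without MEFs array 2, 0.0503 without ESCs array 1 and 0.0509 without O-retro array B. The Sfmbt2 cluster families, near-identical rodent copies, had 7 higher and 3 lower of 64 (6 and 1 adjusted over the list alone; list adjusted p = 0.483), with miR-467a-5p at 2.14 ± 0.25.

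In all, 233 of 763 microRNAs passed in this comparison, 103 higher and 130 lower, and 149 of them differed more than 2-fold. The largest decrease was that of miR-3970, at -4.47 ± 0.36. MEFs array 2 had the brightest empty spots (163), and fewer microRNAs passed without it. Fewer still passed without MEFs array 1 (empty-spot median 41.7), so the drop was not particular to the array with bright background. In 1 pair of control probes (a-PUC2), mismatched spots stood at 5.70% and 7.22% of matched ones on the MEFs arrays. They stood at 4.49% or less on the others.

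**Figure D1:**
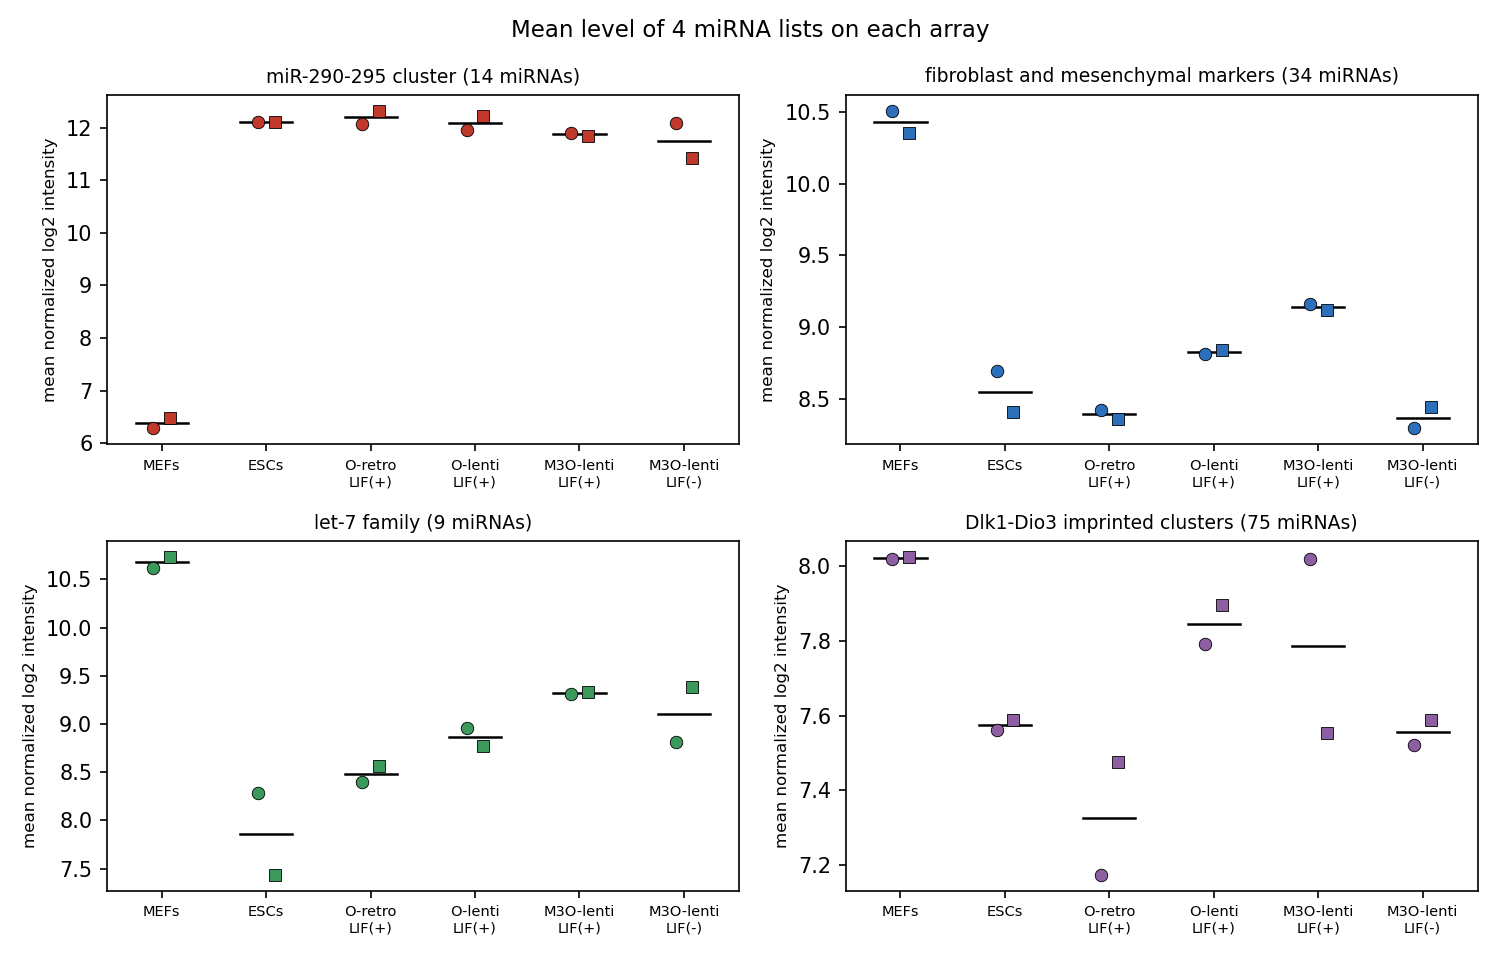
Mean normalized log2 intensity of the members of 4 lists on each array, by group on the horizontal axis, with a circle for array 1 or A, a square for array 2 or B and a line at the group mean (n = 2). The mean of the 14 miR-290 members lies far higher in every pluripotent group than in MEFs. The mean of the 34 fibroblast markers lies higher in MEFs than in every pluripotent group.

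LIF(+) iPSCs were set against ESCs to see how close their microRNA profiles were. 6 of 9 let-7 microRNAs were higher in iPSCs, with let-7d-5p at 1.55 ± 0.27 and let-7f-5p at 1.46 ± 0.30, or 0.96 without ESCs array 2. 5 of 22 members of the miR-17-92 and paralog clusters were lower, with miR-20b-5p at -1.26 ± 0.21 and miR-17-5p at -1.11 ± 0.24. These 4 did not pass without ESCs array 2, the only CGR8 array (adjusted p from 0.175 to 0.31), nor miR-17-5p without ESCs array 1 (0.14), O-retro array A (0.0541), O-retro array B (0.0575) or O-lenti array A (0.0591). The largest increases were those of miR-291b-3p, a member of the miR-290 cluster, at 4.57 ± 0.52, and of miR-5117-5p at 2.92 ± 0.25. The level of miR-291b-3p was 6.53 ± 0.44 in ESCs (log2, SD, n = 2), where 1 of 2 arrays detected it. The largest decrease was that of miR-135b-5p, at -2.30 ± 0.22.

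Of 9 let-7 microRNAs 6 were higher, and 7 adjusted over the list alone (adjusted p = 1.14e-06, and adjusted p = 0.549 with an estimated correlation). let-7e-5p was higher by 1.28 ± 0.26 and let-7g-5p by 1.07 ± 0.22, and the list's median of 1.28 was 0.73 without ESCs array 2. Of 22 members of the miR-17-92 and paralog clusters 5 were lower, and 7 adjusted over the list alone (adjusted p = 5.46e-05, and adjusted p = 0.549 with an estimated correlation). The list's median of -0.26 was -0.49 without ESCs array 1 and -0.16 without M3O-lenti LIF(+) array A. Within the miR-290 cluster 1 member was higher and 2 were lower (1 and 5 adjusted over the list alone), among them miR-291a-3p at -1.44 ± 0.28, and the list did not pass (adjusted p = 0.145). In the fibroblast list 27 of 34 members had positive values, with no member passing, also when adjusted over the list alone. Its median of 0.22 (adjusted p = 0.0108, and adjusted p = 0.613 with an estimated correlation) was -0.081 under 75th percentile scaling, where the median of all microRNAs moved by -0.49. That list's median was 0.43 without ESCs array 1 and 0.081 without ESCs array 2 (adjusted p = 0.347). Single members of other lists passed too, with miR-467a-5p at 1.44 ± 0.26, miR-329-3p at 1.28 ± 0.23, miR-433-3p at 0.86 ± 0.19 and miR-205-5p at 1.04 ± 0.21. Lower ones were miR-96-5p at -1.67 ± 0.29, miR-182-5p at -1.01 ± 0.21, miR-34c-3p at -1.10 ± 0.24 and the neural miR-9-5p at -1.58 ± 0.34. Without ESCs array 2, miR-205-5p still passed and the other 10 microRNAs named in this paragraph did not (adjusted p from 0.106 to 0.349), with let-7e-5p at 0.83 and miR-34c-3p at -0.70. Without ESCs array 1, miR-291a-3p, miR-467a-5p, miR-433-3p, miR-205-5p, miR-96-5p and miR-182-5p did not pass (0.061 to 0.124). Neither did miR-182-5p, miR-34c-3p and miR-9-5p without O-lenti array A (0.0521), or miR-433-3p, miR-34c-3p and miR-9-5p without O-retro array B (0.0575 to 0.0581).

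By limma, 50 of 763 microRNAs passed, 26 higher and 24 lower in iPSCs. The count was 6 without ESCs array 2, which is the only CGR8 array and also had bright empty spots (73.1), 27 without ESCs array 1, 28 without O-lenti array A and 32 without O-retro array B. Without both bright-background arrays (ESCs array 2 and MEFs array 2) fewer still passed. miR-291b-3p then differed by 4.26, beside 4.57 with all arrays, but no longer passed.

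**Figure D2:**
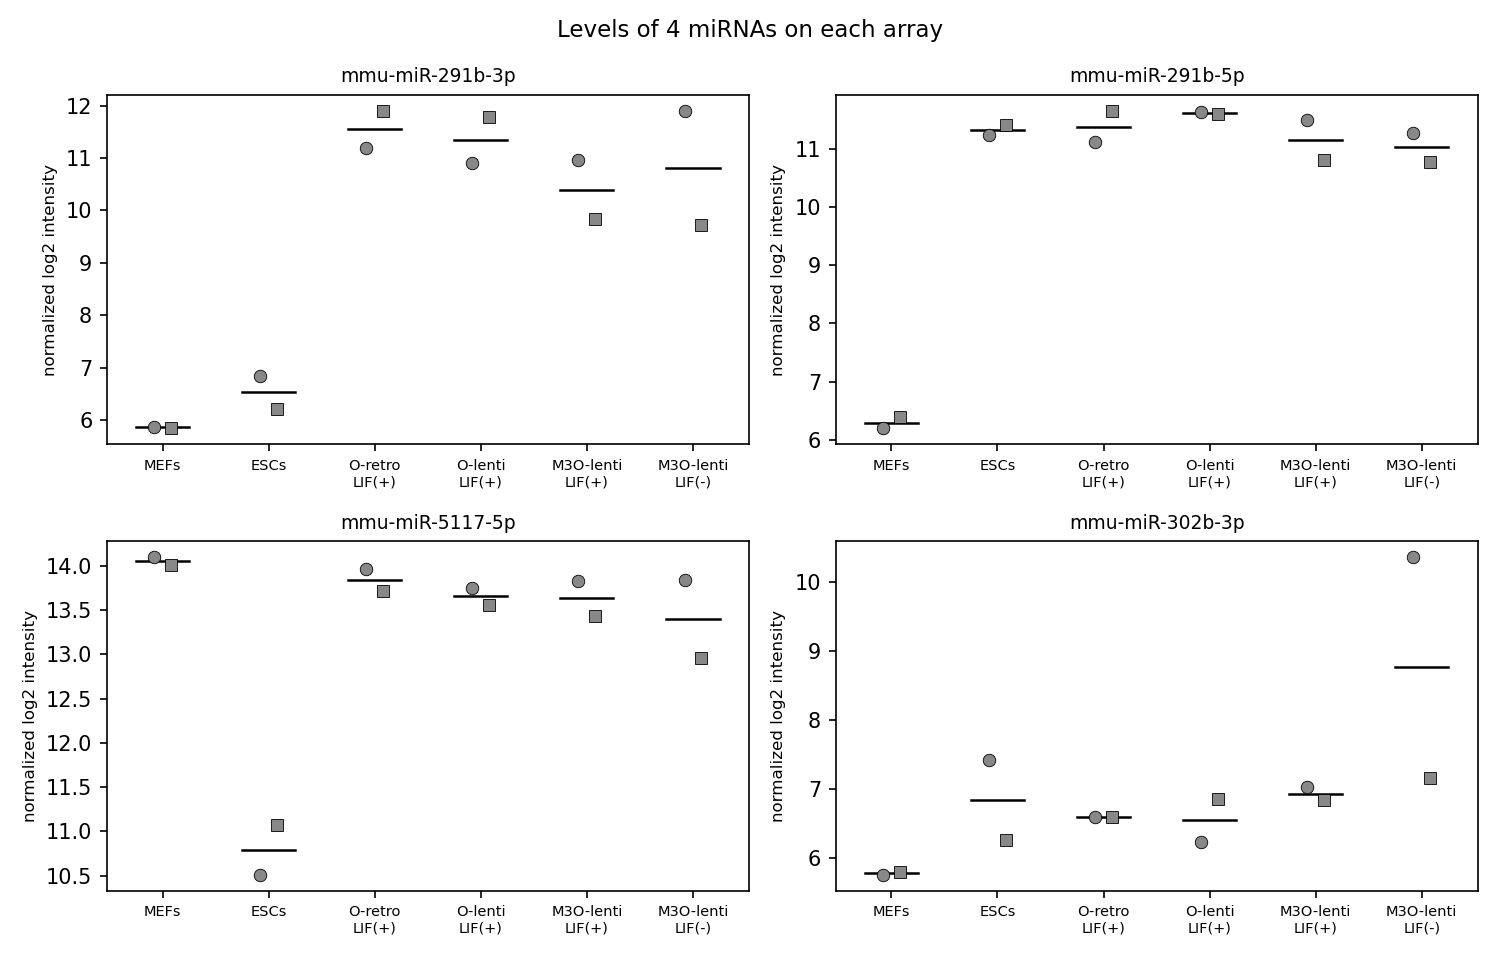
Normalized log2 intensity of 4 microRNAs on each array, by group on the horizontal axis, with a circle for array 1 or A, a square for array 2 or B and a line at the group mean (n = 2). miR-291b-3p and miR-5117-5p lie lower in ESCs than in the iPSCs, miR-291b-5p lies at like levels in ESCs and iPSCs, and miR-302b-3p reaches 10.4 on 1 of the 2 LIF(-) arrays.

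O-lenti iPSCs were set against O-retro iPSCs, which differ in the vector that carries Oct4. The microRNAs of the imprinted Dlk1-Dio3 region were shifted up as a list in O-lenti iPSCs, with 68 of 75 positive and a median of 0.60 (adjusted p = 1.13e-21, and adjusted p = 0.305 with an estimated correlation). Fibroblast markers were also shifted up, with 29 of 34 positive and a median of 0.40 (adjusted p = 1.02e-08, and adjusted p = 0.293 with an estimated correlation). The Sfmbt2 families were shifted down, with 61 of 64 negative and a median of -0.30 (adjusted p = 1.71e-07, and adjusted p = 0.613 with an estimated correlation). By fry the adjusted p was 0.0983 for the Dlk1-Dio3 list, 0.0459 for the fibroblast list and 0.419 for the Sfmbt2 list. No single microRNA passed in limma (75 had an unadjusted p under 0.05, smallest adjusted p 0.211). Values were 1.17 ± 0.23 for miR-433-3p, 1.19 ± 0.28 for miR-329-3p, 0.99 ± 0.22 for miR-29a-3p, 0.88 ± 0.21 for miR-199a-3p and -0.92 ± 0.18 for miR-551b-5p. Adjusted over the list alone, 1 Dlk1-Dio3 microRNA and 5 fibroblast markers were higher, and 0 of the Sfmbt2 families and 0 of let-7 passed. The let-7 family had a median of 0.48 and 8 of 9 positive (adjusted p = 0.0388, and adjusted p = 0.801 with an estimated correlation), a call lost without O-retro array A (median 0.27, adjusted p = 0.21) or O-lenti array A (median 0.30, adjusted p = 0.242). Without O-retro array A the Dlk1-Dio3 median was 0.38.

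M3O-lenti iPSCs were set against O-lenti iPSCs to compare M3O with Oct4 in the same vector and with LIF. Fibroblast markers were shifted up in M3O-lenti iPSCs, with 31 of 34 positive and a median of 0.36 (adjusted p = 1.71e-11, and adjusted p = 0.193 with an estimated correlation). The let-7 family was shifted up too, with 9 of 9 positive and a median of 0.48 (adjusted p = 3.08e-06, and adjusted p = 0.549 with an estimated correlation). Neither list passed by fry (adjusted p = 0.146 for fibroblast markers and 0.442 for let-7). No single microRNA passed in limma (6 had an unadjusted p under 0.05, smallest adjusted p 0.999), and 0 in each of these lists passed when adjusted over the list alone. Values were 0.89 ± 0.32 for miR-146a-5p, 0.66 ± 0.27 for miR-199a-5p, 0.49 ± 0.27 for let-7g-5p, -0.72 ± 0.19 for miR-5130 and -0.48 ± 0.25 for miR-292-3p. Without O-lenti array A miR-292-3p was at -0.72 and without O-lenti array B at -0.23, and let-7g-5p was at 0.32 without M3O-lenti LIF(+) array B. The miR-290 cluster had a median of -0.10 with 9 of 14 negative (adjusted p = 0.0411, and adjusted p = 0.769 with an estimated correlation). That call was lost without M3O-lenti LIF(+) array A (median -0.022, adjusted p = 0.401) or O-lenti array B (median -0.065, adjusted p = 0.816).

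LIF(-) M3O-lenti iPSCs were set against LIF(+) M3O-lenti iPSCs, which were made the same way but with LIF; whether the LIF(-) cells had feeders is not stated. 10 fibroblast markers fell without LIF, led by miR-22-3p at -2.05 ± 0.30 (adjusted p = 0.00957), miR-199a-5p at -1.84 ± 0.27 and miR-222-3p at -1.76 ± 0.31. Another 9 microRNAs rose, led by miR-680 at 2.45 ± 0.46 (adjusted p = 0.025), miR-1956 at 2.01 ± 0.34 and miR-3474 at 1.95 ± 0.40. All 10 microRNAs that fell were members of the fibroblast list. Their median GC content was 47.7%, that of the 9 that rose 66.7%, and that of all microRNAs tested 50%.

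Of 34 fibroblast markers 10 fell, and 17 adjusted over the list alone. The others of the 10 were miR-221-3p at -1.59 ± 0.28, miR-29a-3p at -1.46 ± 0.22, miR-143-3p at -1.46 ± 0.31, miR-199a-3p at -1.40 ± 0.21, miR-24-3p at -1.33 ± 0.29, miR-22-5p at -1.08 ± 0.23 and miR-214-3p at -0.97 ± 0.22. The list had a median of -0.64 (adjusted p = 1.3e-12, and adjusted p = 0.193 with an estimated correlation). The microRNAs that rose included miR-3077-5p at 1.76 ± 0.31, miR-346-3p at 1.74 ± 0.39, miR-5130 at 1.53 ± 0.19, miR-219-2-3p at 1.42 ± 0.31, miR-2861 at 1.23 ± 0.27 and the epithelial miR-205-5p at 1.14 ± 0.25. After a correction of each array for GC content, 14 of the 19 still passed, and miR-2861 was at 0.32 ± 0.17 (adjusted p = 0.396). The Dlk1-Dio3 list had a median of -0.23 with 57 of 75 negative and 0 members passing, also when adjusted over the list alone (adjusted p = 0.00408, and adjusted p = 0.801 with an estimated correlation). Its median was -0.062 without LIF(+) array A (adjusted p = 0.878) and -0.46 without LIF(+) array B. The endoderm and liver list had 3 of 3 negative, a median of -0.87, 0 members passing and 2 lower adjusted over the list alone (adjusted p = 0.0437, and adjusted p = 0.549 with an estimated correlation). That call was lost without LIF(-) array A (adjusted p = 0.207), LIF(+) array A (0.0688) or LIF(+) array B (0.0937). Values of microRNAs that did not pass were -0.70 ± 0.22 for miR-295-3p, -1.40 ± 0.36 for let-7i-5p and 1.83 ± 0.80 for miR-302b-3p, for which the 2 LIF(-) arrays differed (10.4 on A and 7.17 on B). miR-302b-3p was at 0.23 without LIF(-) array A and at 3.43 without LIF(-) array B, where it passed (adjusted p = 0.0183).

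By limma, 19 of 763 microRNAs passed, 9 of them with an adjusted p of 0.0499, next to the threshold. The count was 0 without LIF(-) array A (70 with an unadjusted p under 0.05), 0 without LIF(+) array B (108 with an unadjusted p under 0.05), 3 without LIF(+) array A and 16 without LIF(-) array B.

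**Figure D3:**
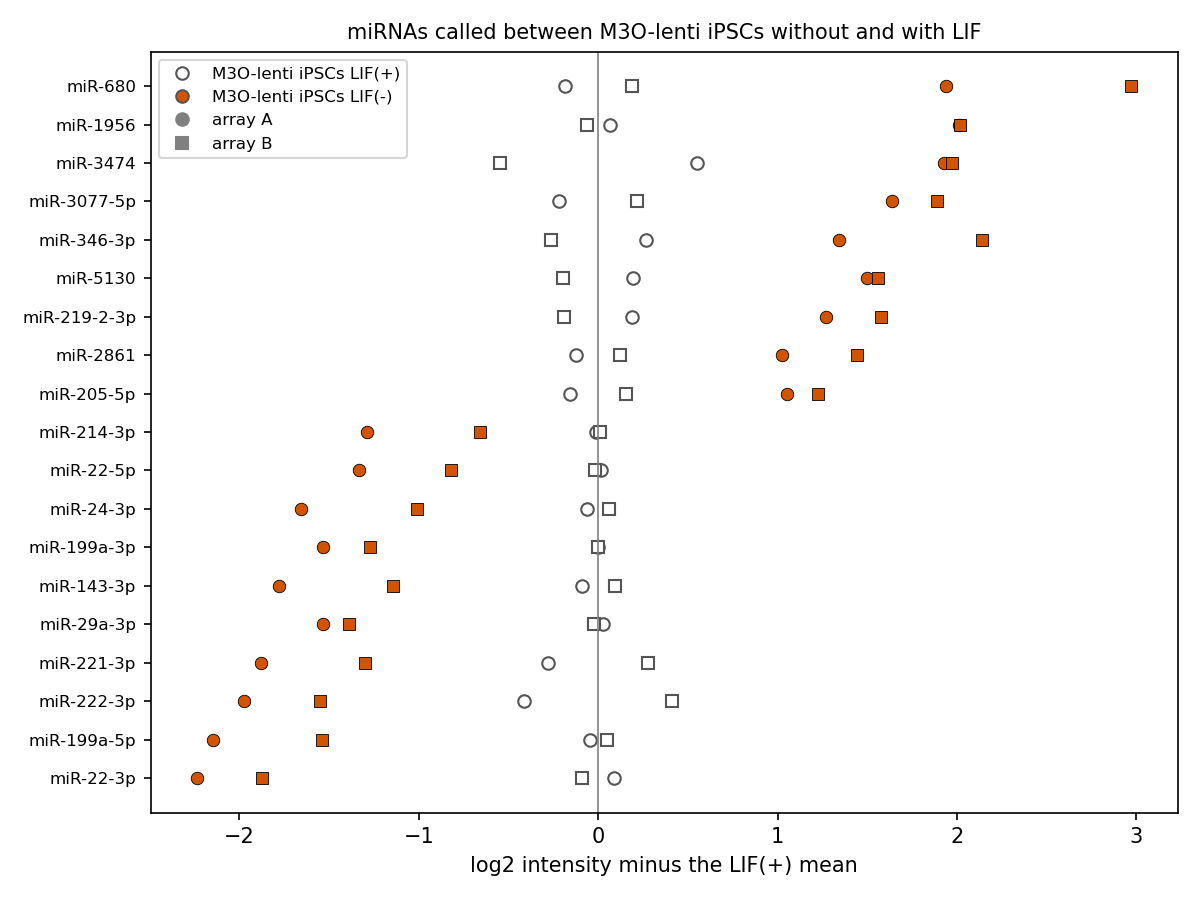
Log2 intensity minus the mean of the 2 LIF(+) arrays, on the horizontal axis, for the 19 microRNAs that passed between LIF(-) and LIF(+) M3O-lenti iPSCs, with open symbols for LIF(+) arrays, filled symbols for LIF(-) arrays, circles for array A and squares for array B. For every one of the 19, both LIF(-) arrays lie on the same side of both LIF(+) arrays.

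LIF(-) M3O-lenti iPSCs were then set against the mean of ESCs and the 3 LIF(+) iPSC groups, to find microRNAs that stand apart in the cells kept without LIF. The epithelial miR-200c-3p (1.80 ± 0.36) and miR-205-5p (1.32 ± 0.20) were higher in LIF(-) cells, as were miR-680 (2.09 ± 0.36), miR-1956 (1.63 ± 0.27) and miR-5130 (1.43 ± 0.15, adjusted p = 0.0022). The fibroblast marker miR-22-3p was lower (-1.36 ± 0.24), and so was miR-295-3p of the ESC cluster (-0.79 ± 0.17). In all 21 microRNAs passed, 16 higher and 5 lower.

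The fibroblast list had 3 members lower, and 12 adjusted over the list alone, with a median of -0.27 and miR-199a-5p at -1.06 ± 0.21 (adjusted p = 4.92e-05, and adjusted p = 0.549 with an estimated correlation). Relative to MEFs its median on the LIF(-) arrays (-2.26 and -2.10) was near those in O-retro iPSCs (-2.20 and -2.24) and ESCs (-2.02 and -2.18) and below those in O-lenti (-1.70 and -1.68) and M3O-lenti LIF(+) iPSCs (-1.30 and -1.31). The miR-200 and miR-205 list had 2 of 8 higher, also adjusted over the list alone, and a median of 0.12 (adjusted p = 0.0388, and adjusted p = 0.698 with an estimated correlation). That call was lost without ESCs array 2 (adjusted p = 0.115), LIF(-) array B (median 0.041, 0.193), M3O-lenti LIF(+) array A (0.0551) or O-lenti array B (0.0531), and its median was 0.24 without LIF(-) array A and 0.061 without O-retro array B. Of the miR-290 cluster 1 member was lower, and 2 adjusted over the list alone. Its median of -0.31 (adjusted p = 0.00775, and adjusted p = 0.698 with an estimated correlation) was 0.021 under 75th percentile scaling, -0.55 without LIF(-) array A and -0.15 without LIF(-) array B (adjusted p = 0.902). The miR-302 list had 3 of 3 positive, a median of 1.35 and 3 higher adjusted over the list alone, but 0 over all microRNAs, with miR-302b-3p at 2.03 ± 0.63 (list adjusted p = 0.0238, and adjusted p = 0.613 with an estimated correlation). Its call was lost without LIF(-) array A (median 7.98e-04, adjusted p = 0.819) or ESCs array 2 (adjusted p = 0.0528), and its median was 2.77 without LIF(-) array B. miR-302b-3p was at 0.44 without LIF(-) array A, and at 3.63 without LIF(-) array B, where it passed (adjusted p = 0.00362). The median let-7 level relative to MEFs was -1.44 and -0.93 on the LIF(-) arrays, near the -1.21 and -1.29 of M3O-lenti LIF(+) iPSCs. It was -1.49 and -1.85 in O-lenti iPSCs, -2.38 and -2.20 in O-retro iPSCs and -2.63 and -3.59 in ESCs. The let-7 list had 7 of 9 positive, a median of 0.83 and 5 higher adjusted over the list alone, but 0 over all microRNAs, with let-7e-5p at 1.02 ± 0.25 (list adjusted p = 0.0121, and adjusted p = 0.766 with an estimated correlation). Without LIF(-) array B its median was 0.44 (adjusted p = 0.363), and let-7e-5p passed without ESCs array 1 (adjusted p = 0.0411) or O-lenti array A (adjusted p = 0.0499). The endoderm and liver list had 3 of 3 negative, a median of -0.65 and 3 lower adjusted over the list alone, but 0 over all microRNAs (adjusted p = 0.0388, and adjusted p = 0.549 with an estimated correlation). That call was lost without LIF(-) array A (adjusted p = 0.285), ESCs array 1 (0.0569), ESCs array 2 (0.0591), O-lenti array A (0.06) or O-retro array A (0.0612). Other microRNAs that passed were miR-183-5p at 1.35 ± 0.28, miR-219-2-3p at 1.35 ± 0.24, miR-363-5p at 1.01 ± 0.20, miR-18b-3p at 0.84 ± 0.17 and miR-301a-3p at -1.03 ± 0.23.

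The count of 21 was 1 without O-retro array B, 2 without LIF(-) array A, 4 without LIF(-) array B, 9 without O-lenti array B and 10 without ESCs array 2. The call of miR-301a-3p was lost on leaving out any 1 of the 10 arrays compared (-0.98 to -1.08). That of miR-295-3p was lost on leaving out any ESCs, O-retro or LIF(-) array, O-lenti array B or M3O-lenti LIF(+) array B (-0.73 to -0.85). That of miR-183-5p was lost with the same arrays except M3O-lenti LIF(+) array B (1.1 to 1.6). miR-680, miR-1956, miR-200c-3p, miR-205-5p and miR-22-3p lost theirs without O-retro array B or any LIF(-) array. Against O-lenti iPSCs alone 0 passed in limma (95 had an unadjusted p under 0.05), and against ESCs alone 62.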

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

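The tests of hybridization stringency, of the GC-rich part of the higher microRNAs, of feeder RNA for miR-291b-3p and of a strain variant were chosen after the results were seen.

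A signal above the empty spots appeared in mismatched control spots, which the comparisons do not use. Its share of the matched spots differed between control pairs, and the pairs did not all rank the arrays alike. For PUC2 the mismatched and matched spots were at 12360.7 and 16435.4 on LIF(-) array A and at 6293.94 and 12599.7 on LIF(-) array B. The share was thus lower on B, as in the a-PUC2 pair. For PUC2-20B, whose mismatched spots were dim, it was higher on B (74.6 and 13337.1 on A, 38.4 and 4033.11 on B). In the a-PUC2 pair, without background subtraction, the share was highest on MEFs array 2 (7.22%) and lowest on LIF(-) array B (0.197%). It was 5.70% on MEFs array 1, 4.49% and 3.83% on the ESCs arrays, 2.79% on LIF(-) array A against 1.02% on M3O-lenti LIF(+) array A, and 0.206% on M3O-lenti LIF(+) array B.

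Fibroblast microRNAs fell in LIF(-) M3O-lenti iPSCs, by a median of -0.64 against LIF(+) ones; relative to MEFs their median was -2.26 and -2.10 on the LIF(-) arrays, beside -2.20 and -2.24 in O-retro iPSCs, -2.02 and -2.18 in ESCs, -1.70 and -1.68 in O-lenti iPSCs and -1.30 and -1.31 in LIF(+) M3O-lenti iPSCs, all 4 on feeders. A GC trend between arrays as the whole cause is argued against by the median of -0.55 after a GC correction (adjusted p = 5.63e-11), with 9 of the 10 lower calls still passing. Less RNA from MEF feeder cells in the LIF(-) samples is a candidate explanation. 52 other MEF-enriched microRNAs, chosen without M3O arrays, had a median of -0.35, with 40 of 52 below 0 and 0 called lower. For 95 in 100 of 10000 random lists matched on level the median was -0.13 to 0.13. Such lists do not keep the shared behaviour of MEF-enriched microRNAs. Lower expression in the iPSCs themselves would give the same shift, so it does not tell the 2 apart. The let-7 family, also high in MEFs, decides nothing, since its members went both ways (median -0.025, 5 of 9 below 0), with let-7i-5p at -1.40 ± 0.36 (adjusted p = 0.0729), let-7g-5p at -1.03 ± 0.27 (adjusted p = 0.079) and 2 lower adjusted over the list alone. An effect of LIF omission on the iPSCs themselves stays open and untested, since the feeder status of the LIF(-) cells is not given in the sources used here.

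The 9 microRNAs that rose in LIF(-) cells were mostly GC-rich (median GC content 66.7%), and after the GC correction their median went from 1.74 to 1.25. It kept more of its size than the bound set beforehand allowed for a GC trend as the whole cause. In all 5 of 9 still passed, the fewest that counted against it in that bound. Of these 5 only 3 were above 60% GC, so the count says little about the GC-rich ones. Of the 7 above 60% GC, with a median of 1.76 before (median SE 0.34) and 1.25 after (median SE 0.31), 3 still passed: miR-680 went from 2.45 ± 0.46 to 2.22 ± 0.40 (adjusted p = 0.0236), miR-1956 from 2.01 ± 0.34 to 1.85 ± 0.31 (adjusted p = 0.0228) and miR-3077-5p from 1.76 ± 0.31 to 1.11 ± 0.21 (adjusted p = 0.0265). The other 4 did not: miR-2861 went from 1.23 ± 0.27 to 0.32 ± 0.17, miR-5130 from 1.53 ± 0.19 to 0.89 ± 0.20 and miR-346-3p from 1.74 ± 0.39 to 1.25 ± 0.34 as their differences shrank, and miR-3474 from 1.95 ± 0.40 to 1.79 ± 0.43, which left its adjusted p at 0.0551. Less stringent hybridization cannot be told apart from a difference between the cells either. In the a-PUC2 pair, mismatched spots were at 2.79% of matched ones on LIF(-) array A and 0.197% on B. The 9 differed by a median of -0.25 (SD 0.35, 9 of 9 below 0), A minus B. A microRNA raised on A alone would be less apt to pass, so these 9 do not decide it. For the GC-rich part, a GC trend and a difference between the cells cannot be told apart, because the correction took away part of the difference and fewer than 4 of the 7 kept their call.

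miR-291b-3p and miR-5117-5p were lower in ESCs than in LIF(+) iPSCs. The bright background of ESCs array 2, the only CGR8 array, is argued against, since without it the differences were 4.26 (adjusted p = 0.0387) and 3.20 (adjusted p = 0.00371), though miR-291b-3p had an adjusted p of 0.0972 when MEFs array 2 was left out too. RNA from feeder cells is argued against for miR-291b-3p, which neither MEFs array detected and which was at least 27.4-fold higher in LIF(+) iPSCs; for miR-5117-5p, at 14.1 in MEFs, it was not tested. A strain variant in the sequence the probe reads cannot be told apart from lower expression: the other arm, miR-291b-5p, differed by 0.058 ± 0.23 (adjusted p = 0.893), and no genotype was used here. A difference between the ESC lines and the MEF-derived iPSCs stays open and untested.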

How the results depend on the processing

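The background from empty spots, the GC correction and the leaving out of both bright-background arrays were chosen after seeing the data; the other settings were planned. For pluripotent cells against MEFs every setting kept the count of 233 within 1.5 times, and O-lenti against O-retro and M3O-lenti against O-lenti stayed at 0 by limma under every setting (75 and 6 at an unadjusted p under 0.05 with all arrays). The 75th percentile scaling moved the median of all microRNAs by 0.13 (pluripotent against MEFs), -0.49 (iPSCs against ESCs), 0.12 (O-lenti against O-retro), 0.30 (LIF(-) against LIF(+)) and 0.14 (LIF(-) against the others). Under it the 50 calls of iPSCs against ESCs (26 higher, 24 lower) became 10 (2 and 8), the 19 of LIF(-) against LIF(+) (9 and 10) became 10 (7 and 3) and the 21 of LIF(-) against the others (16 and 5) became 12 (12 and 0). It reversed miR-21-5p against MEFs (0.24), the fibroblast list in iPSCs against ESCs (-0.081) and the miR-290 cluster in LIF(-) cells against the others (0.021). For iPSCs against ESCs, cyclic loess gave 24 and leaving out the bright-background arrays 4 (1 and 3). For LIF(-) against LIF(+), no detection filter gave 5 (1 and 4), with more microRNAs tested, the values processed by the authors 30, the background from empty spots 11, and a fit of the compared groups alone 0 by limma, with fewer arrays to estimate the spread (13.9% of those tested had an unadjusted p under 0.05). For LIF(-) against the others, no filter gave 1, ESCs alone 62 (36 and 26), O-lenti alone 0 (95 at an unadjusted p under 0.05) and leaving out the bright-background arrays 9 (5 and 4). Of the list tests 27 passed, 16 with microRNAs detected on all arrays, 0 with an estimated correlation and 13 with fry. The 13 included the neural and blood cell lists against MEFs, which had not passed in camera. Beyond what those constructions show, the cause was not tested.

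Leaving out 1 array at a time gave 162 to 245 calls for pluripotent cells against MEFs, 6 to 51 for iPSCs against ESCs, 0 to 0 for O-lenti against O-retro and for M3O-lenti against O-lenti, 0 to 16 for LIF(-) against LIF(+), 1 to 29 for LIF(-) against the others, and 21 to 31 list tests. A lone array was assumed to vary like the other groups. The letters A and B were not taken as pairs, since that required A minus B to correlate over 0.1 between every 2 iPSC groups and 4 of the 6 did (lowest -0.11). The highest, 0.41, was that of M3O-lenti LIF(+) with LIF(-). With the replicate block on the iPSC arrays LIF(-) against LIF(+) had 28 calls, against 20 without it, and the other comparisons among iPSCs had 0. The files gave no slide or scan batch, so no batch block was run. Signal over background limits dim microRNAs, and the fewest microRNAs were detected on ESCs array 2 (498), M3O-lenti LIF(+) array B (553) and MEFs array 2 (595).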

Other observations

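No test in this part was chosen after the result was seen. In pluripotent cells against MEFs the muscle, neural, endoderm and liver, and blood cell lists did not pass in limma's camera. By fry the neural (adjusted p = 0.00778) and blood cell (adjusted p = 0.0338) lists passed. The neural list had 2 of 5 higher, also adjusted over the list alone (list adjusted p = 0.0934). The blood cell list had 3 higher and 2 lower of 7, or 4 and 2 adjusted over the list alone (list adjusted p = 0.392), and the endoderm and liver list 2 higher and 1 lower of 3, also adjusted over the list alone (list adjusted p = 0.761). Among 4 muscle microRNAs 0 passed, also adjusted over the list alone (list adjusted p = 0.94), and among 6 members of the p53-regulated miR-34 family 0 passed (list adjusted p = 0.98). The muscle list, with 4 of 13 microRNAs on the array tested, was of interest because M3O carries a MyoD domain. In M3O-lenti against O-lenti iPSCs 4 of 4 were negative with 0 passing (list adjusted p = 0.279). In LIF(-) against LIF(+) M3O-lenti iPSCs both sides carried M3O. There the list had 0 of 4 passing and 1 higher adjusted over the list alone (list adjusted p = 0.41).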
